A study of Mus musculus with 24 samples.

How the data were processed

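The series holds 24 chromatin immunoprecipitation sequencing (ChIP-seq) libraries of mouse leukaemia cells that carry a NUP98 fusion. NUP98 is a nuclear pore protein whose gene is rearranged in a group of acute myeloid leukaemias. Cells were treated with VTP50469, a small molecule that blocks the binding of menin to the histone methyltransferase MLL1, or with the solvent DMSO. Peak lists exist for 14 libraries, and the other 10 are sequenced input chromatin, for which no peak list was used here. The 14 lists form 7 pairs of DMSO and VTP50469: MLL1 in the cell lines NUP98-HOXA9, NUP98-HOXD13, NUP98-JARID1A and NUP98-NSD1, Menin in NUP98-HOXA9 and NUP98-HOXD13, and trimethylated lysine 4 of histone H3 (H3K4me3) in NUP98-HOXA9. Per the labels, the dose was 2 µM except in NUP98-NSD1, where it was 200 nM although the treatment protocol of the series names 2 µM. The labels give a time of 96 h except for MLL1 in NUP98-HOXA9. There the DMSO label gives 72 h and the label of the treated library gives no time, so 72 h was assumed for it. Samples were grouped by the cell line, antibody, agent and time in the labels, and by the assumed time for that library.

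Per the submitters' processing notes, the tools named are bcl2fastq 2.20.0.422, STAR 2.7.5a, Picard 2.9.4, SAMtools, MACS2 and bedtools, and the genome build is mm10. The role and settings of each tool, and which input served as the control of which list, are not given in the sources used here. NUP98-NSD1 has an input of VTP50469 cells alone, and in NUP98-HOXA9 both 96 h inputs are of VTP50469 cells and the 72 h input is of DMSO cells. Each list belongs to 1 library, per the labels, so peaks were called per sample and not on pooled samples. Each row of a deposited list gives an interval, a score, a fold enrichment, −log10 values of p and q, and a summit. The fold of each peak is the authors' own ratio, as deposited, and is used here only to describe, rank or filter peaks within 1 list. The exception is a closing paragraph that sets the median fold of treated lists beside that of their DMSO lists. The deposited −log10 q of a list's weakest peak lay between 2.00 and 2.07 in the 14 lists, so a region that is absent from a list had either no enrichment or enrichment below this limit. The deposited score equals 10 times the −log10 q, rounded down, and was not used. Read depth is unknown from peak lists, and a difference in depth or in immunoprecipitation between 2 libraries changes how many peaks pass the limit.

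Rows of a list that overlapped were to be merged to 1 region, and no rows overlapped. A DMSO region was counted as lost when it shared no base with any region of the VTP50469 list of the same pair (minimum overlap 1 bp). Shares of regions are given with 95% Wilson intervals. With 1 library per condition there is no replicate check, no p-value was computed, and the intervals cover counting error over regions only. Genes came from the RefSeq gene table of assembly GRCm38.p6, which is the build of the lists, with 21631 protein-coding genes on chromosomes 1 to 19 and X. The plan was to use a window around the 5′ end of each gene. The table gives no strand, so windows of 1 kb either side of both annotated ends of each gene were used in place of promoters and are called gene ends. A gene end is lost when a region lies in its windows in DMSO and none after VTP50469, gained in the opposite case, and kept when both lists have one. The table holds gene starts and ends only, so regions were not assigned to exons, introns or untranslated regions. The covered length of a gene is the number of bases from its start to its end, plus 2 kb on both sides, that lie in regions. Over a gene list it is summed over the members, so bases that lie within 2 kb of more than 1 member are counted more than once, mainly in the Hox clusters. Counted once, Hoxb genes had 33031 bp of MLL1 in the DMSO list of NUP98-HOXA9 instead of 47466 bp. Covered length is a length and not a level of binding, and it depends on how much was called in each library, so both lengths are given.

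There were 16 gene lists, fixed before the data were examined: the Hoxa, Hoxb, Hoxc and Hoxd clusters, menin-MLL leukaemia targets, HOX cofactors, stem and progenitor regulators, myeloid differentiation genes, erythroid and megakaryocyte markers, lymphoid markers, mast cell and basophil markers, MLL and menin complex genes, cell cycle regulators, MHC class II genes, housekeeping genes and ribosomal protein genes. Some genes stand in more than 1 list, for example Meis1, Pbx3, Myc, Cdk6 and Lmo2. The percent of a list's bound gene ends that were lost is given with its percentile among 10000 random lists of the same size, drawn from genes bound in DMSO and matched on decile of fold. Lists with fewer than 3 bound members have no percentile. The mean log2 ratio of covered length, with 200 bp added to both lengths, was placed in the same way among 10000 random lists matched in 50 bins of DMSO covered length. A test in the closing section also matched on the mean fold of the covered bases, in 4 bins within each bin of length. These percentiles describe the libraries and are not p-values. Random lists draw genes one by one, while neighbouring Hox genes share regions and change together. Percentiles of the Hox clusters can therefore be too extreme. Overlaps between lists of genes are given beside n1 × n2 / N, the number that independent lists would share.

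The rule for named genes was also fixed before the data were examined. It takes 14 genes whatever their values (Hoxa7, Hoxa9, Hoxa10, Meis1, Pbx3, Mef2c, Cdk6, Flt3, Jmjd1c, Myc, Cebpa, Gata2, Actb and Gapdh). It adds, per pair, the 8 lost genes with the highest DMSO fold, the 5 gained genes with the highest VTP50469 fold, and the 5 genes with the largest fall in covered length. Genes lost in all 4 MLL1 pairs complete it. Many genes that the rule put first had a region whose boundary moved across the edge of the window while the region itself was called in both lists. For lost and gained genes the text therefore names those whose own region shares no base with the other list, a choice made after the data were seen, and the counts follow the original definition. Genes of the fixed lists given as examples beyond this rule, and the genes with the largest gain in covered length, were chosen after their values were seen.

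Covered length was planned with 2 kb on the upstream side alone, which the missing strand also ruled out. Alternatives tried were a limit of −log10 q of at least 5, lists trimmed to equal length by fold, at least 50% of a region covered, unmerged rows, chromosomes 1 to 19 and X alone, VTP50469 regions extended by 500 bp, windows of 3 kb, and random lists without matching. The definition by the region itself, the equal lengths and the limit of 5 applied to covered length, bases counted once over a list, and overlaps of lost genes matched on decile of fold in both lines, were chosen after the data were seen. The alternative of any annotated transcript start was not run, since the gene table holds no transcript starts. Overlap and list functions were tested on simulated data made from the real DMSO lists: the lost regions were recovered in all 7 pairs, a planted list of lost genes reached a percentile of at least 99.98, and between 2 and 7 of 100 random lists per pair lay outside the central 95%. Simulated loss did not depend on fold, so the simulation checks the functions and not whether matching on decile of fold is fine enough. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.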

Results

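Binding of MLL1 was mapped in 4 mouse leukaemia lines with different NUP98 fusions, binding of Menin in 2 of them and H3K4me3 in 1, each in DMSO and after VTP50469. The question was how blocking the contact between menin and MLL1 changes where these proteins sit on the genome. Each condition had 1 library, so the values below have no replicate error. The number of called regions is the only depth that the lists show. DMSO lists of MLL1 held 22534 regions in NUP98-HOXA9, 20154 in NUP98-HOXD13, 15765 in NUP98-JARID1A and 7113 in NUP98-NSD1. After VTP50469 the same lines gave 21739, 14744, 24950 and 1036 regions. Menin lists held 9050 regions in DMSO and 403 after VTP50469 in NUP98-HOXA9, and 18826 and 16706 in NUP98-HOXD13. H3K4me3 lists held 9443 and 9567 regions.

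**Figure D1:**
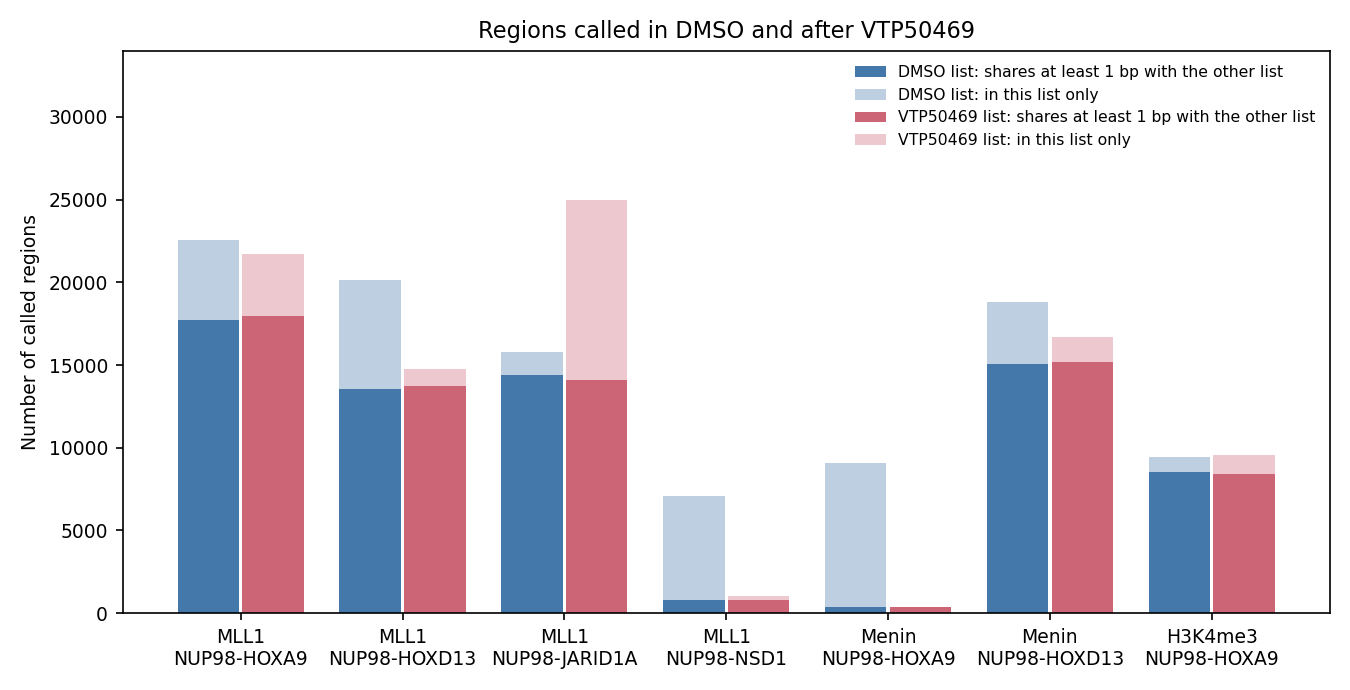
Number of called regions (vertical axis) in the DMSO list (blue) and the VTP50469 list (red) of each of the 7 pairs; dark parts share at least 1 bp with the other list of the pair and pale parts do not. The treated lists of MLL1 in NUP98-NSD1 (1036 regions) and of Menin in NUP98-HOXA9 (403 regions) are the shortest, and that of MLL1 in NUP98-JARID1A is longer than its DMSO list.

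In NUP98-HOXA9 cells, VTP50469 for an assumed 72 h left most MLL1 sites called, and wide MLL1 domains were shorter, those over leukaemia genes among them. Of all 375 genes with at least 4 kb in MLL1 regions in DMSO, 224 (59.7%) had at most 50% of that length after treatment. Meis1, which encodes a DNA-binding partner of HOX proteins (chromosome 11, 18880428 to 19019651), had 10718 bp in MLL1 regions in DMSO and 984 bp after treatment. Pbx3, another HOX partner (chromosome 2, 34171457 to 34372045), went from 22035 to 8505 bp, and the cell cycle kinase gene Cdk6 from 15593 to 4004 bp. The housekeeping genes Actb and Gapdh had 2353 and 2116 bp in DMSO and 2325 and 2126 bp after treatment. The longest losses of covered length were at Foxp1, a forkhead transcription factor gene (31785 to 7813 bp), Zcchc7 (22547 to 1402 bp), the sialyltransferase gene St8sia4 (20736 to 1959 bp), Tox (20513 to 2530 bp) and Pde4d, a phosphodiesterase gene (24671 to 7958 bp).

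Of the 22534 MLL1 regions in NUP98-HOXA9, 4834 were not called after VTP50469, which is 21.5% (95% Wilson interval 20.9% to 22.0%), and 3756 of the treated list were called only there. Regions of 2 kb or wider numbered 547 in DMSO and 103 after treatment, while all regions together covered 15.5 Mb and 12.4 Mb. Of the 10% of DMSO regions with the lowest fold 70.1% were lost, and of the 10% with the highest fold none. Among gene ends, 9725 had a DMSO region, of which 382 were lost, 9343 kept, and 398 others were gained.

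Menin-MLL leukaemia targets, genes known from MLL-rearranged leukaemia, had 153478 bp in MLL1 regions in NUP98-HOXA9 in DMSO and 52341 bp after VTP50469, or 34.1%. Covered length was shorter at 23 members and at most 50% of the DMSO length at 18 of the 26 with a region. The mean log2 ratio lay at percentile 0.03 of the matched random lists. Examples are Eya1 (7191 to 974 bp), Mef2c (5385 to 1259 bp), Jmjd1c (4191 to 1220 bp) and Myc (3252 to 1488 bp). At gene ends 6 of 20 bound members were lost (30.0%, interval 14.5% to 51.9%, percentile 99.9), among them Flt3, which encodes a growth factor receptor. Stem and progenitor regulators went from 102221 to 37540 bp, at a percentile of the mean below 0.01, with 4 of 18 gene ends lost. Erg, an ETS factor gene, had 15760 bp and then 820 bp, and Gata2 had 2398 bp in DMSO and no region after treatment. Over the 77 ribosomal protein genes with a region, 91.8% of the covered length was left, and over the 25 housekeeping genes 87.0%.

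Other lists in NUP98-HOXA9 spanned this range. HOX cofactors kept 38.4% of the 35517 bp they had in DMSO, most of which lay at Meis1 and Pbx3, and the remaining 6 members with a region in either list had at most 1334 bp each in DMSO. MLL and menin complex genes kept 52.1%, with Mllt3 at 11006 and 1895 bp, while Kmt2a, the gene of MLL1 itself, had 943 and 958 bp. Cell cycle regulators kept 56.4%, and Cdkn1b, a cell cycle inhibitor gene, had 5133 and 1632 bp. Myeloid differentiation genes kept 92.1%, although Cebpa, a myeloid transcription factor gene, had 2338 and 860 bp. MHC class II genes kept 91.4%, erythroid and megakaryocyte markers 88.2% and lymphoid markers 96.0%. Mast cell and basophil markers had 866 and 1209 bp.

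Among genes of NUP98-HOXA9 whose own MLL1 region was absent after VTP50469, the 8 with the highest DMSO fold were Vwa5a (10.5), Galnt1 (9.92), Tmem229b (9.64), Gsn (9.36), Irgm1 (9.36), Rab38 (9.07), Olfml2b (8.79) and Rad54l (8.79). New regions with the highest VTP50469 fold lay at Dlx4 (17.5), Csta3 (17.5), Vmn1r219 (15.6), and at Prn and Prnp (13.6), which share 1 region. Csta3 and Vmn1r219 belong to families of similar genes, so their reads are uncertain.

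At the Hoxa cluster on chromosome 6, the NUP98-HOXA9 DMSO list had a single MLL1 region of 23187 bp from 52211278 to 52234464, which reached from the end of Hoxa3 over Hoxa7 and Hoxa9 into Hoxa10. The locus held 4 regions in DMSO and 14 after VTP50469, the widest of these of 3255 bp. Hoxa9 had 8274 and 5322 bp, Hoxa7 6951 and 4980 bp, and Hoxa10 5268 and 2164 bp. Covered length summed over the Hoxa cluster genes was 61.8% of that in DMSO, over the Hoxb cluster 49.0% and over the Hoxc cluster 60.4%, or 62.1%, 49.4% and 57.6% when bases that neighbouring genes share were counted once. The mean log2 ratios lay at percentiles 49.0, 47.6 and 97.2 of random lists of like covered length, so that none was shorter than such genes in general. No Hoxd gene had an MLL1 region in this line.

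**Figure D2:**
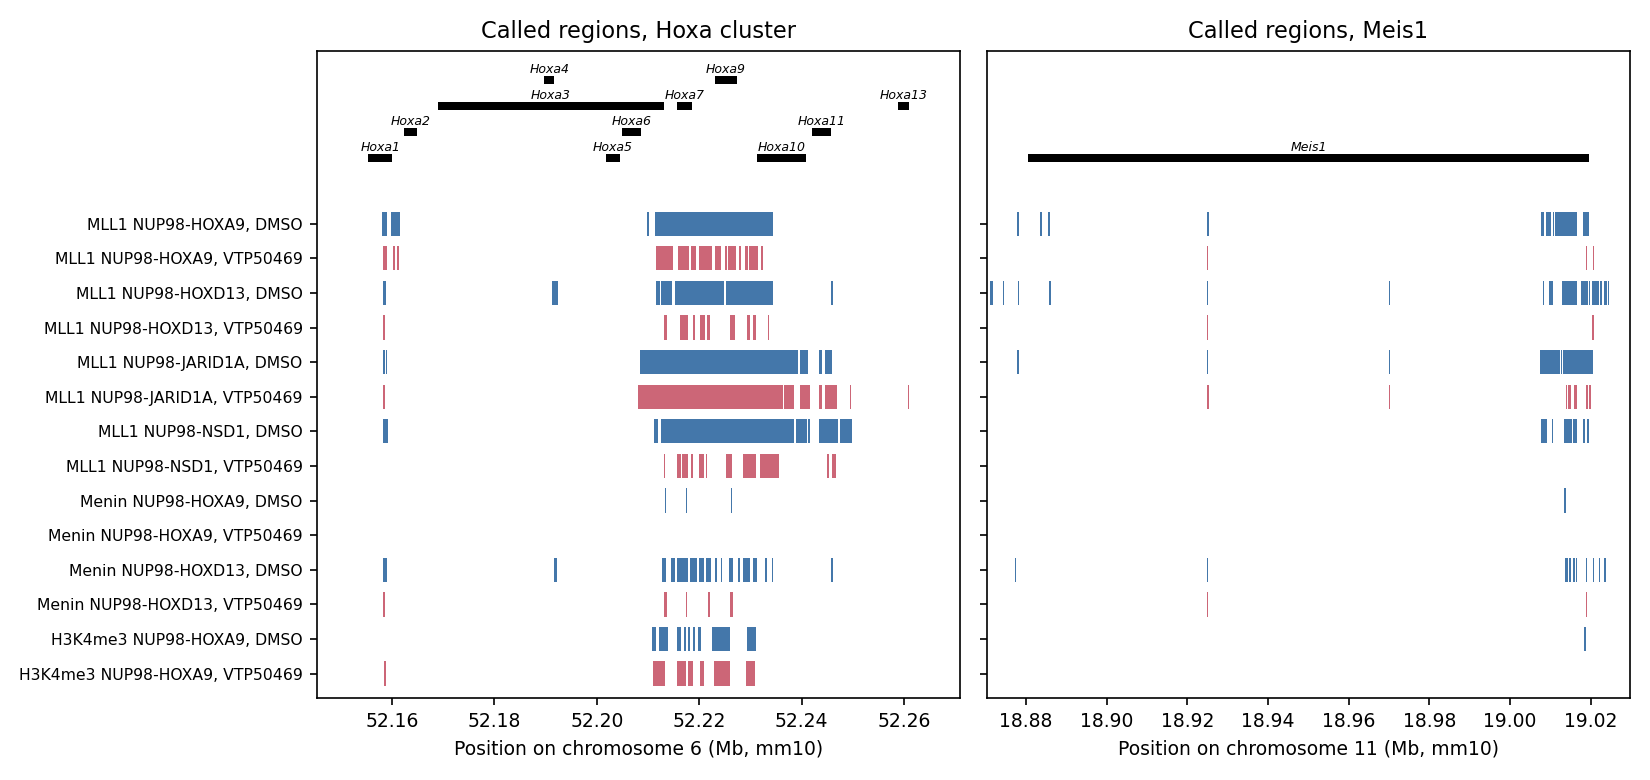
Called regions along the Hoxa cluster (left, chromosome 6) and Meis1 (right, chromosome 11), in Mb of mm10, with 1 line per list; blue bars are DMSO regions, red bars VTP50469 regions and black bars annotated genes. The wide MLL1 domain over Hoxa7 to Hoxa10 is broken into regions of at most 3255 bp after VTP50469 in NUP98-HOXA9 and remains 28319 bp wide in NUP98-JARID1A, and the MLL1 domain at the right end of Meis1 is smaller or absent after VTP50469 in all 4 lines.

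In NUP98-HOXD13 cells, 96 h of VTP50469 came with a shorter MLL1 list and shorter covered lengths over the same kinds of gene. Meis1 had 9331 bp in DMSO and 678 bp after treatment, Pbx3 15141 and 2224 bp, Mef2c 8518 and 1382 bp, and Cdk6 9270 and 2398 bp. Hoxa9 had 7742 and 1722 bp, Hoxa10 5280 and 1305 bp, and Hoxa7 6442 and 2355 bp. Gapdh had 2356 and 1960 bp. Actb had 2320 and 2141 bp, a ratio of 0.923 that was 1.41 with lists of equal length.

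Of the 20154 MLL1 regions in NUP98-HOXD13, 6582 were lost, or 32.7% (interval 32.0% to 33.3%), against 2453 (16.6%) with lists of equal length. Regions of 2 kb or wider went from 292 to 50, and the total covered from 13.0 to 7.61 Mb. Of 189 genes with at least 4 kb in DMSO, 155 (82.0%) had at most 50% of it after treatment. Gene ends with a region numbered 9872 in DMSO, of which 1205 were lost, and 122 were gained (699 and 378 with lists of equal length). The longest losses of covered length were at Foxp1 (15995 to 2637 bp), Pbx3, Runx2, a bone and blood transcription factor gene (13427 to 1669 bp), Akap13 (12621 to 1340 bp) and Dach1 (9242 to 321 bp). With lists of equal length the ratio was 0.283 at Foxp1 (0.165 in full lists), 0.0533 at Dach1 (0.0347) and 0.319 at Mef2c (0.162).

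Menin-MLL leukaemia targets in NUP98-HOXD13 had 129375 bp in DMSO and 26272 bp after VTP50469, or 20.3%, with 23 of 25 covered members at 50% or less and a percentile of the mean of 0.04. Jmjd1c had 3210 and 649 bp, Myc 2429 and 990 bp, and Flt3 1355 and 551 bp. Ratios in lists of equal length were 0.323 at Jmjd1c (0.202 in full lists and 0.108 with −log10 q of at least 5), 0.792 at Myc (0.408) and 0.167 at Gata2 (0.0994). At their ends 9 of 22 bound genes were lost (40.9%, interval 23.3% to 61.3%, percentile 97.4). Stem and progenitor regulators kept 26.9% of the covered length (percentile 0.40), with Gata2 at 3580 and 356 bp and Mecom at 5165 and 0 bp. The Hoxa cluster kept 25.3%, the Hoxb cluster 32.6% and the Hoxc cluster 40.2%, at percentiles of 5.90, 13.5 and 62.8. HOX cofactors kept 21.2%, cell cycle regulators 46.7%, MLL and menin complex genes 54.1%, and myeloid differentiation genes 66.4%, with Cebpa at 1985 and 760 bp. Ribosomal protein genes kept 70.2% and housekeeping genes 75.3%.

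Genes of NUP98-HOXD13 that lost their own MLL1 region, in order of DMSO fold, were Rtcb (16.4), Tnfrsf1b (16.4), Nek2 (16.1), Diaph2 (13.7), Ndufa12 (13.4), Slc12a4 (13.4), Pus1 (12.7) and Parp14 (12.3). Tnfrsf1b encodes a receptor of tumour necrosis factor and Nek2 a mitotic kinase. New regions lay at Abca13 (fold 12.3), St6galnac3 (11.8), the histidine ammonia-lyase gene Hal (10.6), Ankrd22 (10.0) and Pirb (9.78), which has near-identical relatives.

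In NUP98-JARID1A cells the MLL1 list was longer after 96 h of VTP50469, and yet Meis1 was covered over 13134 bp in DMSO and 3582 bp after treatment (562 bp with lists of equal length). The other long losses were at Elf1, an ETS factor gene (15297 to 6985 bp), Eya1, a transcriptional coactivator gene (9907 to 1693 bp), Dcun1d1 (8396 to 1934 bp) and Crlf3 (7577 to 2760 bp). The Hoxa cluster kept its MLL1 domain. Hoxa9 and Hoxa7 had 8274 and 6951 bp in both lists, which is the whole length counted for these genes, so a gain there could not show. The widest region of the locus was 30990 bp in DMSO and 28319 bp after treatment. Hoxa10 had 11721 and 10994 bp, and the ratio over the cluster was 1.04 (0.976 with lists of equal length). Gains in covered length were longest at the corepressor gene Bcor (12200 to 20517 bp), Zmiz1 (5420 to 11806 bp), Rin3 (1588 to 7561 bp), Creb5 (1431 to 6636 bp) and Hoxb3 (5753 to 10852 bp).

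Of the 15765 MLL1 regions in NUP98-JARID1A, 1359 were lost, or 8.62% (interval 8.19% to 9.07%), and 10874 of the 24950 treated regions (43.6%) were called only after VTP50469. With lists of equal length, 3417 regions were lost. Regions of 2 kb or wider numbered 686 and 645. At gene ends 91 were lost and 1442 gained. This balance turned with lists of equal length, to 930 lost and 497 gained, and 150 were lost with the limit of −log10 q of at least 5.

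Menin-MLL leukaemia targets in NUP98-JARID1A had 160359 bp in DMSO and 127870 bp after treatment, or 79.7%, when all genes together stood at 131%. The percentile of the mean was 33.8. None of their 20 bound gene ends was lost in full lists (percentile 46.2), and 20.0% were lost with lists of equal length (percentile 99.97). Covered length was shorter at 17 members and longer at 12, and Jmjd1c had 6736 and 3729 bp, Rnf220 14582 and 10718 bp, Cdk6 9573 and 9196 bp, and Flt3 316 and 1173 bp. Mef2c had 293 and 947 bp and Pbx3 274 and 947 bp, so that both were little covered in this line. Lists of equal length gave a ratio of 0.255 at Jmjd1c (0.554 in full lists), 1.78 at Flt3 (3.71) and 1.75 at Mef2c (3.23). Stem and progenitor regulators had a ratio of 1.01 (0.801 with lists of equal length), and Gata2 had 9916 and 10043 bp (a ratio of 0.992 with lists of equal length). Hoxb cluster genes stood at 170%, housekeeping genes at 132% and ribosomal protein genes at 132%. Myeloid differentiation genes stood at 163%, with the granule protein gene Ltf at 101 and 1092 bp, the integrin gene Itgam at 300 and 1371 bp and Cebpe at 731 and 2788 bp, while Mpo (1370 bp) and Elane (461 bp) had no region after treatment. Cebpa had 3092 and 3087 bp, Myc 5730 and 5935 bp (a ratio of 0.965 with lists of equal length), Actb 1651 and 3188 bp, and Gapdh 1555 and 3547 bp.

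Genes of NUP98-JARID1A that lost their own MLL1 region included the Wnt antagonist gene Frzb (fold 12.1 in DMSO), 2610318N02Rik (10.0), Papss2 (9.62), Mrpl16 (8.99), Tespa1 (8.85), Lair1 (8.47), Dnaaf3 (7.70) and Septin6 (7.70). New regions were strongest at Dnase2b (26.6), Mgat5b (26.4), the neutrophil antigen gene Cd177 (26.2), Cfp (26.2) and LOC115490339 (26.2).

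In NUP98-NSD1 cells, treated with 200 nM for 96 h, few MLL1 regions were called after VTP50469 at genes of any kind. Meis1 had 6189 bp in DMSO, Cdk6 5327 bp, Jmjd1c 3628 bp, Pbx3 1664 bp, and Myc and Cebpa 1548 bp each, and none of them had a region after treatment. Part of the Hoxa domain was still called, with 8274 and 2280 bp at Hoxa9, 11762 and 5580 bp at Hoxa10, and 6951 and 2766 bp at Hoxa7. Ribosomal protein genes lost all 27 bound gene ends, and housekeeping genes lost 10 of 14. Gapdh had 1971 and 440 bp and Actb 757 and 452 bp.

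Of the 7113 MLL1 regions in NUP98-NSD1, 6314 were lost, or 88.8% (interval 88.0% to 89.5%), and 706 of 1036 (68.1%) with lists of equal length. Of 4770 gene ends with a DMSO region 4112 were lost and 120 gained, a balance that turned to 483 lost and 536 gained in lists of equal length. Menin-MLL leukaemia targets kept 2.73% of 39144 bp (a ratio of 0.0570 with lists of equal length), at a percentile of the mean of 1.46, and all genes together kept 9.40%. At gene ends 9 of 10 bound members were lost, at percentile 64.5. The Hoxa cluster kept 33.4% of its covered length, at percentile 99.7, which can be too extreme since neighbouring Hoxa genes share regions. The Hoxb cluster kept 7.60%, stem and progenitor regulators 3.91%, cell cycle regulators 14.3% and housekeeping genes 15.8%. With lists of equal length the ratios were 0.0916 for stem and progenitor regulators, 0.501 for cell cycle regulators, 0.742 for MLL and menin complex genes (0.192 in full lists) and 0.766 for housekeeping genes (2927 to 2243 bp). Hoxd genes had 311 bp in DMSO and no region after treatment. Mef2c, Flt3 and Gata2 had no MLL1 region in either list.

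The longest losses of covered length in NUP98-NSD1 were at Foxp1 (19274 to 1719 bp), Etv6, an ETS factor gene (16228 to 815 bp), Coro2a (15840 to 3352 bp), Hoxb3 (14019 to 2499 bp) and Hoxb6 (9056 to 558 bp), with ratios of 0.187 at Foxp1, 0.118 at Etv6 and 0.102 at Hoxb6 in lists of equal length, and 0.0261 at Etv6 with −log10 q of at least 5 (0.0502 in full lists). Genes that lost their own region, in order of fold, were Trim56 (25.8), Uba7 (19.8), Il1rap (18.6), Dock8 (18.2), Cmpk2 (17.8), Cdkn2c (17.4), Fut8 (16.7) and Trim25 (16.3). New regions lay at Plekho2 (13.0), at Hnrnpc and Rpgrip1, which share 1 region (9.90), at Camta1 (8.55) and at Cdk4 (8.55).

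**Figure D3:**
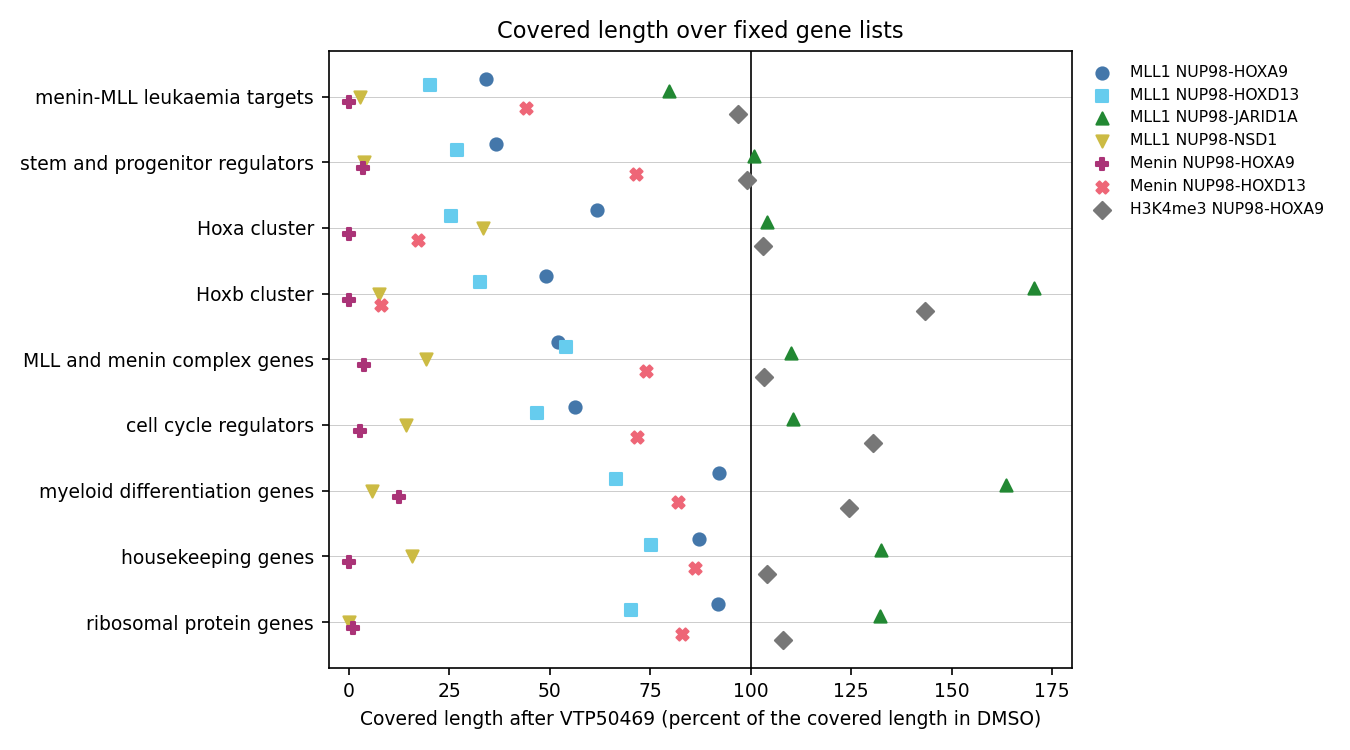
Covered length after VTP50469 as a percent of that in DMSO (horizontal axis, linear) over 9 of the fixed gene lists (vertical axis), with 1 symbol per pair and a line at 100%. MLL1 in NUP98-HOXA9 and NUP98-HOXD13 sits at 34.1% and 20.3% for menin-MLL leukaemia targets and at 87.0% and 75.3% for housekeeping genes.

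Menin itself was called over far fewer places after VTP50469 in NUP98-HOXA9 cells. Of 9050 regions, 8681 were lost, or 95.9% (interval 95.5% to 96.3%), and 233 of 403 (57.8%) with lists of equal length. All 61 bound ribosomal protein genes, all 17 bound housekeeping genes and all 7 bound menin-MLL leukaemia targets lost Menin at their ends, while Hoxd genes and mast cell and basophil markers had no Menin region. Gene ends with a region went from 6015 to 210, with 5809 lost and 4 gained (161 and 106 with lists of equal length). Menin covered length in DMSO was 1663 bp at Pbx3, 1435 bp at Gapdh, 687 bp at Cdk6, 560 bp at Myc, 544 bp at Actb, 457 bp at Meis1, 405 bp at Mef2c and 372 bp at Flt3, and no region was called at these genes after treatment. Hoxa9 had 255 bp and Hoxa7 245 bp in DMSO, and neither had a Menin region after treatment. Hoxa10, Jmjd1c, Cebpa and Gata2 had no Menin region in either list. Losses of covered length were longest at Gse1 (4061 to 0 bp), Hoxb3 (3605 to 0 bp), Nfic (2617 to 0 bp), Mnt (2783 to 232 bp) and Vmp1 (2488 to 0 bp).

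Lost Menin regions in NUP98-HOXA9 with the highest fold lay at Arhgap1 and Zfp408, which share 1 region (45.0), and at Fbp2 (35.3), Ccdc97 (34.7), Oosp2 (32.2), Ginm1 (31.8), Rpl31 (31.8) and Esd (31.5). The 4 gained genes were Ndufb10 and Rps2, which share 1 region (5.10), Sfi1 (2.65) and Speer4e (2.59), a member of a family of near-identical copies. Regions of 2 kb or wider held 49.2% of the bases of the treated list and 3.85% of those of the DMSO list. They numbered 22 and 26, with 147046 and 149324 bp, so that their total length was much the same in both. Of the 403 treated regions 58 lay off chromosomes 1 to 19 and X, and no region was removed here for its place. The widest treated region, 37903 bp on chromosome 9 from 3000187 to 3038089, overlaps no protein-coding gene of the table. Regions at this place are among the 3 widest of every list except the DMSO list of Menin in NUP98-HOXD13.

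In NUP98-HOXD13 cells Menin stayed called at most sites but over shorter stretches of the HOX and leukaemia genes. Pbx3 had 6907 bp in DMSO and 521 bp after VTP50469, Hoxb3 5536 and 682 bp, Hoxa7 4846 and 380 bp, Eya1 3412 and 317 bp, and Hoxb8 3354 and 0 bp, the 5 longest losses. Hoxa9 had 3602 and 1117 bp, Meis1 2888 and 679 bp, Hoxa10 2069 and 0 bp, and Jmjd1c 1425 and 723 bp. Under the limit of −log10 q of at least 5 the ratio was 0.237 at Jmjd1c (0.507 without it) and 0.133 at Meis1 (0.235). Myc had 1251 and 1186 bp, Cebpa 629 and 630 bp, Gapdh 1810 and 1766 bp, and Gata2 1040 and 394 bp. Mef2c (2592 and 1115 bp), Cdk6 (3875 and 2254 bp) and Actb (2002 and 1702 bp) had ratios of 0.430, 0.582 and 0.850 in full lists and of 1.05, 1.11 and 1.12 in lists of equal length, where Pbx3 stood at 0.163 (0.0754 in full lists) and Eya1 had 1582 and 317 bp.

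Of the 18826 Menin regions in NUP98-HOXD13, 3759 were lost, or 20.0% (interval 19.4% to 20.5%), and 2301 (13.8%) with lists of equal length. At gene ends 850 of 9720 were lost and 132 gained (629 and 210 with lists of equal length). Menin-MLL leukaemia targets kept 44.2% of 56090 bp, at a percentile of the mean below 0.01, and 7 of 18 gene ends were lost (38.9%, interval 20.3% to 61.4%, percentile 96.1). The Hoxa cluster kept 17.2%, the Hoxb cluster 8.07% and the Hoxc cluster 31.8% of the covered length, with percentiles below 0.01, below 0.01 and of 2.75. These percentiles can be too extreme, because neighbouring Hox genes share regions and the random lists do not allow for it. Stem and progenitor regulators kept 71.4%, cell cycle regulators 71.6%, MLL and menin complex genes 74.0%, ribosomal protein genes 82.8% and housekeeping genes 86.1%. Lost regions of the highest fold lay at Il4ra (17.3), Ccdc102a (16.6), Coprs (16.4), Trim44 (16.4), Snai3 (15.7), Mavs (15.4), Whrn (15.0) and Tulp3 (14.5). New ones lay at Ankrd22 (12.7), 1110002E22Rik (10.6), Tcn2 (9.47), Vmn1r219 (9.37) and Glt1d1 (9.06).

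H3K4me3, a mark of active gene starts, was called over similar total lengths in both conditions of NUP98-HOXA9, with the Hoxa cluster near its DMSO length and the Hoxb and Hoxc clusters above it in total. Hoxa9 had 3580 and 3481 bp, Hoxa10 1854 and 1773 bp, Hoxa7 2764 and 3071 bp (1827 and 3071 bp, a ratio of 1.68, with −log10 q of at least 5), Cdk6 4004 and 4192 bp, Myc 3076 and 4529 bp, and Cebpa 3207 and 3948 bp. Meis1 had 587 bp in DMSO and no region after VTP50469. The longest losses were at Rnf220 (3519 to 901 bp), the hepatocyte growth factor gene Hgf (2450 to 0 bp), Zfp978 (4211 to 2202 bp), Rabgap1l (3734 to 1903 bp) and Pbx3 (3545 to 1804 bp), and Jmjd1c had 3147 and 1517 bp. In lists of equal length the ratio was 0.147 at Rnf220 (0.256 in full lists) and 0.211 at Rabgap1l (0.510). Mef2c had 1158 and 539 bp, but its ratio of 0.465 was 1.10 with the limit of −log10 q of at least 5. Hoxb8 had the longest gain, from 620 to 3619 bp, and Hoxb6, Hoxb7 and Hoxb9 also gained a gene end region. Hoxb4 had 910 and 2356 bp and Hoxc8 1156 and 2469 bp, while Hoxb5 had 3927 and 2688 bp and Hoxb3 8572 and 8535 bp.

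Of the 9443 H3K4me3 regions, 907 were lost, or 9.60% (interval 9.03% to 10.2%), and 1161 of the treated list were new. Their median width was 713 bp in DMSO and 757 bp after treatment. At gene ends 318 of 8057 were lost and 631 gained. Menin-MLL leukaemia targets kept 96.8% of 48833 bp. Their mean log2 ratio was −0.21, at percentile 1.40, while the median was 0.02, since 6 of the 23 covered members were at 50% or less and 15 members were longer after treatment. At gene ends 3 of 16 were lost (18.8%, interval 6.59% to 43.0%, percentile 99.1, or 93.0 with windows of 3 kb). The Hoxb cluster stood at 143%, the Hoxc cluster at 124%, the Hoxa cluster at 103%, cell cycle regulators at 130%, myeloid differentiation genes at 124%, ribosomal protein genes at 108% and housekeeping genes at 104%. Lost regions of the highest fold lay at Aopep (9.28), Trappc12 (8.44), Ctso (8.01), Trmt10b (8.01), Nipsnap1 (7.80), Gm3325 (7.59), Syngr1 (7.59) and Abcd4 (7.38), and new ones at Mif (9.80), Litaf (9.37), Mrps25 (8.95), Nfkbib (8.81) and Cdk5rap2 (8.67). Actb had 1615 and 2005 bp, Gapdh 2205 and 2899 bp, and Gata2 318 and 0 bp.

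Most gene ends with Menin in DMSO also had MLL1. In NUP98-HOXA9 these were 5985 of 6015 (99.5%), or 61.5% of the gene ends with MLL1 and 2.21 times the 2704 expected of independent lists. In NUP98-HOXD13 both were called at 9325 gene ends, 95.9% of those with Menin and 94.5% of those with MLL1, or 2.10 times the 4436 expected. The expected numbers count all 21631 genes, many without either protein, and both ratios lie near the highest possible. Counted by regions, 96.9% of Menin regions in NUP98-HOXA9 (interval 96.5% to 97.2%) shared bases with MLL1. In NUP98-HOXD13 83.4% did (interval 82.9% to 84.0%). Of gene ends that had MLL1 without Menin in DMSO, 470 of 547 lost MLL1 in NUP98-HOXD13 (85.9%, interval 82.8% to 88.6%), against 735 of 9325 with Menin (7.88%, interval 7.35% to 8.45%). In NUP98-HOXA9 the counts were 380 of 3740 (10.2%, interval 9.23% to 11.2%) and 2 of 5985 (0.0334%, interval 0.00916% to 0.122%). These comparisons are not matched on fold. The median MLL1 fold was 15.1 with Menin and 5.79 without it in NUP98-HOXD13, and 20.1 and 8.51 in NUP98-HOXA9, and regions of low fold were lost most often. Menin and MLL1 libraries of a line came from different run dates, and in NUP98-HOXA9 from 96 h and 72 h, the latter assumed for the treated library. The labels of NUP98-HOXA9 also name the cells of the MLL1 libraries differently from those of the Menin and H3K4me3 libraries. They were taken as the same line.

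Many genes had MLL1 in all 4 lines in DMSO. Of the 21631 genes, 4536 had an MLL1 region at a gene end in all 4 lines, 11.3 times the 403 expected of independent lists, 4116 in 3, 1008 in 2 and 763 in 1. The expected number counts all genes, and 11208 had no MLL1 region at a gene end in any line. Lists that favour the same genes for any reason share many, so the ratio says little about these lines in particular. With all lists cut to the 7113 regions of the shortest, 2759 were shared by all 4. Among genes bound in both lines, 201 were lost in both NUP98-HOXA9 and NUP98-HOXD13, 21 in both NUP98-HOXA9 and NUP98-JARID1A, and 33 in both NUP98-HOXD13 and NUP98-JARID1A. Independent lists would share 22.0, 1.15 and 3.50, but regions of low fold were lost more often than those of high fold in each line, so that weak genes would overlap without a shared effect. Matched on decile of DMSO fold in both lines, the numbers expected were 119, 5.86 and 17.8, so that the counts were 1.69, 3.59 and 1.85 times these. With NUP98-NSD1, where most gene ends were lost, the counts were near those expected: 110 against 99.8 for NUP98-HOXA9, 314 against 291 for NUP98-HOXD13 and 19 against 16.3 for NUP98-JARID1A, or 111, 318 and 17.4 when matched on fold. Only Tgtp2, which has a near-identical copy, Bag2 and Mvb12b were lost in all 4 lines, each with a fold of at most 7.88 in any DMSO list. Doses and times differed between lines as stated above.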

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

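The tests in this part were chosen after the result was seen, except those of random lists matched on covered length in NUP98-HOXA9 and NUP98-HOXD13. The test on the strength of regions new in NUP98-JARID1A was written before it was run, but the comparison with other pairs was added after its values were seen. In NUP98-JARID1A several MLL1 values went the opposite way from the other 3 lines, with 1 library per condition, and the differences between lines were not tested. The ratio of VTP50469 to DMSO was 1.58 for the number of regions and 1.47 for the bases covered. Over gene lists the ratio of covered length was 1.04 for the Hoxa cluster, 1.70 for the Hoxb cluster, 1.01 for stem and progenitor regulators, 1.63 for myeloid differentiation genes, 1.10 for MLL and menin complex genes and 1.10 for cell cycle regulators. With lists of equal length 4 of these turned, to 0.976 for the Hoxa cluster, 0.801 for stem and progenitor regulators, 0.982 for MLL and menin complex genes and 0.999 for cell cycle regulators. The ratio was 1.36 for MHC class II genes, 1.32 for housekeeping genes and 1.32 for ribosomal protein genes. Over lists with little MLL1 it was 2.63 for erythroid and megakaryocyte markers, 1.51 for lymphoid markers and 3.52 for mast cell and basophil markers, where NUP98-HOXA9 also stood above 1, at 1.40.

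The longer MLL1 list of NUP98-JARID1A has a candidate technical explanation, higher sensitivity of the treated library. Regions called only after VTP50469 had the lower fold, with an area under the curve of 0.841 for shared against new regions, but this was so in every pair (0.629 to 0.866 in the others), and the area does not decide. It does not account for Meis1, where the ratio of covered length was 0.273 when a more sensitive library would give a longer one. Housekeeping and ribosomal protein genes, both at a ratio of 1.32, lengthened with the whole list, which a more sensitive library would also give. For this general rise the technical explanation stays open. What differs between the cell lines, including the fusion partner, stays open as an untested biological explanation, and Menin was not measured in this line.

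The short treated lists of MLL1 in NUP98-NSD1 and of Menin in NUP98-HOXA9 may come from lower sensitivity of these libraries, from wide loss of binding, or from both. Lost regions had the lower DMSO fold in every pair. The area under the curve for kept against lost regions was 0.767 for Menin and 0.694 for MLL1, the lowest areas of all pairs. The highest was 0.902, so that the area does not decide. Of DMSO regions in the top decile of fold, 73.3% were lost for Menin and 61.3% for MLL1. In every other pair this share was at most 0.127%. Strong regions were thus lost too, which does not tell lower sensitivity from wide loss while read depth is unknown. A loss limited to menin-MLL leukaemia targets does not by itself account for either list, since 100% of the ribosomal protein genes with a DMSO region lost it, but such a loss together with lower sensitivity stays open. With lists of equal length the ratio of covered length in NUP98-NSD1 was 0.0570 for these targets, 0.766 for housekeeping genes and 0.742 for MLL and menin complex genes. Only the DMSO list was cut, to its regions of highest fold, which left 18744 bp at the targets and 2927 bp at housekeeping genes. The contrast may follow from this ranking and does not show a selective loss. Lower sensitivity and general loss of MLL1 cannot be told apart in NUP98-NSD1, because each pair has 1 library and read depth is unknown.

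Shorter MLL1 domains over menin-MLL leukaemia targets in NUP98-HOXA9 and NUP98-HOXD13 were set against technical explanations. The mean log2 ratio of the list lay at percentile 0.03 and 0.04 of random lists drawn from the same bins of DMSO covered length. The 50 bins held about equal numbers of genes, so all 189 genes with at least 4 kb in NUP98-HOXD13 fell in the same bin. The widest genes were thus matched coarsely, and the test cannot exclude a general loss that grows with width. Of all genes with at least 4 kb, 59.7% and 82.0% also had at most 50% left. Lower sensitivity would shorten weak and wide domains first, and among random lists matched on both covered length and mean fold the list still lay at percentiles 1.39 and 0.47. These are nearer the middle than with length alone, and the same bins of length were used. Median fold was not lower after treatment, at 10.7 against 8.26 in DMSO in NUP98-HOXA9 and 10.5 against 8.57 in NUP98-HOXD13. The treated lists held 21739 regions against 22534, and 14744 against 20154. These medians depend on which regions were called. Fold is that of a summit and not of the flanks of a domain, so that a part played by sensitivity stays open. A selective effect of VTP50469 on these domains may add to it, as a hypothesis found and tested on the same single libraries, and replicate libraries with a spike-in could test it.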

How the results depend on the processing

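Alternatives applied to covered length, the matching of shared losses on fold, and the definition of lost and gained genes by the region itself, were chosen after the data were seen, the others before. Lists of equal length moved the most results. Lost regions then numbered 2453 for MLL1 in NUP98-HOXD13, 3417 in NUP98-JARID1A and 706 in NUP98-NSD1, and for Menin 233 in NUP98-HOXA9 and 2301 in NUP98-HOXD13. Lost gene ends of MLL1 numbered 699, 930 and 483 in these 3 lines and of Menin 161 in NUP98-HOXA9, and gained ones 378, 497, 536 and 106. Menin-MLL leukaemia targets lost 20.0% of 20 bound gene ends in NUP98-JARID1A. In NUP98-NSD1 they lost 100%, but of 3 bound gene ends alone, and their covered ratio was 0.0570. MLL1 gene ends in all 4 lines numbered 2759. These follow in part from the shorter lists compared.

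Ratios of covered length that changed direction with equal length were, for MLL1 in NUP98-HOXD13, mast cell and basophil markers 2.18 and Actb 1.41. In NUP98-JARID1A they were the Hoxa cluster 0.976, stem and progenitor regulators 0.801, MLL and menin complex genes 0.982, cell cycle regulators 0.999, Myc 0.965 and Gata2 0.992. For Menin they were myeloid differentiation genes 1.04 in NUP98-HOXA9, and in NUP98-HOXD13 mast cell and basophil markers 1.71, Mef2c 1.05, Cdk6 1.11 and Actb 1.12. With −log10 q of at least 5, Actb was 1.41 in the MLL1 pair of NUP98-HOXD13, H3K4me3 over MLL and menin complex genes 0.989 and over Mef2c 1.10, and 150 gene ends lost MLL1 in NUP98-JARID1A. Counted by regions, 15706 Menin regions of NUP98-HOXD13 shared bases with MLL1, or 83.4%, beside 95.9% of the gene ends with Menin. Regions and gene ends are different units, so the 2 counts are not comparable. The cause of the changes in direction was not tested.

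Of the other values, 288 with equal lists, 243 with the stricter limit and 168 with 3 kb windows stayed near the main value. So did 69 with unmatched random lists. A percentile counted as near when it kept its side of, or place in, the central 95%. All 7 values each with 50% of a region covered, extension by 500 bp and chromosomes 1 to 19 and X also stayed near. The 7 with unmerged rows could not differ, since no rows overlapped. A further 87 values moved, among them 2 percentiles that crossed the middle, erythroid and megakaryocyte markers for Menin in NUP98-HOXD13 from 99.9 to 39.7 with 3 kb windows and menin-MLL leukaemia targets for MLL1 in NUP98-JARID1A from 46.2 to 99.97 with equal lists. The Hoxb ratio of MLL1 in NUP98-JARID1A was 1.60 with shared bases counted once (1.70 as a sum). Any annotated transcript start was not run. Read depth is unknown, so its part was not tested.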

Other observations

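The tests in this part were planned, and the list of genes shorter in all 4 lines was chosen after the data were seen. In all 4 MLL1 pairs 80 genes had at most 50% of their DMSO covered length after VTP50469, of which 15 had at least 2 kb in each DMSO list. No expected number was computed for them. In NUP98-NSD1 98.1% of genes with at least 4 kb in DMSO met this limit, so that line removed few. Of the 15, 1110059E24Rik and Abhd17b are neighbours that share regions. The 15 also include Meis1, Elf1, Skap2, a neighbour of the Hoxa cluster, and St8sia4. Skap2 had 16305 and 7015 bp in NUP98-HOXA9, 6757 and 1407 bp in NUP98-HOXD13, 3986 and 1888 bp in NUP98-JARID1A, and 6150 and 0 bp in NUP98-NSD1. Elf1 had 9848 and 3376, 7099 and 1496, 15297 and 6985, and 6063 and 0 bp in the same order.

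One hypothesis was that H3K4me3 narrows in NUP98-HOXA9 at the genes where MLL1 did. Over the 214 of 224 genes with at least 4 kb of MLL1 in DMSO and at most 50% of it after VTP50469 that had an H3K4me3 region in DMSO, the mean log2 ratio of H3K4me3 covered length was −0.11, against −0.00 over all genes, at percentile 0.24 of matched random lists. The medians were −0.03 and 0.04, and 114 of the 214 genes were shorter. The random lists were matched on H3K4me3 covered length alone, and wide MLL1 genes that did not narrow were not compared. The test therefore cannot tell narrowing of MLL1 from wide MLL1 in DMSO. The shift is small, and MLL1 and H3K4me3 were taken at 72 h (assumed for the treated MLL1 library) and 96 h. A link may exist without being shown to be direct.

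Another hypothesis was that Menin in NUP98-HOXD13 narrows where MLL1 did. Over the 154 of 155 such genes with a Menin region in DMSO the mean log2 ratio of Menin covered length was −0.86, against −0.33 over all genes, and 150 were shorter. No random list of 10000 had a lower mean (percentile 0). The random lists were matched on Menin covered length alone, and wide MLL1 genes that did not narrow were not compared. The test therefore cannot tell narrowing of MLL1 from wide MLL1 in DMSO. Loss of both proteins from the same domains may underlie the shorter Menin lengths, and it was not tested in replicate libraries.

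A further question was whether the same wide genes narrow in NUP98-HOXA9 and NUP98-HOXD13. Of 148 genes with at least 4 kb of MLL1 in both DMSO lists, 87 and 117 had at most 50% after VTP50469 and 83 had so in both, 1.21 times the 68.8 expected of independent lists. The bound of 1.5 times that was set could not be reached, since at most 87 genes can be shared, so the test decides nothing.

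Wide regions recurred at the same places. On chromosome 9 one of 37887 bp from 3000197 to 3038083 had a fold of 2.10 in the DMSO list of MLL1 in NUP98-HOXA9, and one of 38086 bp stood in the treated H3K4me3 list. On chromosome X a region of 17458 bp from 169989978 to 170007435, near Mid1, had a fold of 7.14 in the treated list of MLL1 in NUP98-HOXA9, and regions at this place had a fold of up to 17.9, in the DMSO list of Menin in NUP98-HOXD13.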
